A study of Mus musculus with 6 samples.

How the data were processed

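RNA was extracted with the RNeasy Micro Kit from wild-type C57BL/6 mouse duodenal crypt organoids given vehicle or 100 ng/ml BMP2 on day 6 for 24 h, and libraries were made with a BGI kit, per the labels' protocols. The labels give 3 libraries per condition and do not say whether these came from separate cultures or animals. Any q-value then measures only the spread between these samples, which may be technical. Transcripts were quantified with kallisto 0.46.1 and the build mm39 was named, per the submitters' processing notes. The column names are those of the R package IsoformSwitchAnalyzeR. Its version, the annotation release, the statistical test behind the q-values, the filters and the strand setting are not given in the sources used here.

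One table of the authors' own comparison was used. Isoform fractions were computed by the authors for each condition, as the isoform's share of its gene's abundance. The difference of the fractions, BMP2 minus vehicle, was also computed by the authors, and it departs from the printed fractions by at most 0.001. The q-value of each usage change is the authors', per the file headers. TPM values, abundances scaled to the total of all transcripts, are the authors' means over the libraries of a condition, per the file headers. The ranks of the listed isoforms run to 380, with 78 absent, and isoforms outside the 302 listed were not analysed here. Every listed isoform has a q under 0.05, an absolute difference of at least 0.101 and a mean TPM over both conditions of at least 1.00, and its gene is marked as having a predicted consequence. The mean TPM of the listed isoforms has a median of 5.70. Values per library were not used here, so no standard deviation, pairing or test across libraries could be computed. Depth per library is unknown. TPM keeps no trace of depth, so the precision of a fraction could not be derived. The design planned a test across libraries with the authors' q-values as the fallback, and the fallback was used. The condition names given in the table's rows carry the same batch label for both conditions.

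The thresholds, a q of 0.05 and an absolute difference of 0.1, were set before the data were examined. Usage is printed as a percent, 100 times the deposited fraction. An implied gene level per condition was computed as the summed mean TPM of the listed isoforms divided by their summed fraction, for genes with both sums above 0 in both conditions, which left out 7 genes. Isoforms of the same gene gave levels that differed by a median of 0.485% in vehicle (84 genes) and 0.346% in BMP2 (77 genes), and at most by 5.18% and 12.7%, for fractions of at least 0.05. A gene was counted as higher or lower when its log2 ratio was over 1 or under -1, with no test. Only the class comparison in genes higher in BMP2 counted a rise of any size.

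Isoforms were matched by stable transcript identifier to GENCODE M21 (GRCm38), which gave names, transcript classes, exons and coding lengths. Of 302 isoforms 297 matched, 294 of them with a version 1 step higher and 3 with a version 2 steps higher in the deposited table, so exon ends may differ slightly from the models used by the authors. The 5 without a match, of Psmc2, Acp2, Tpst2 and Aqp4, stayed out of structure and class comparisons. Coordinates are 1-based GRCm38 positions, and none was converted between builds. In each gene with opposite changes, the isoform with the largest gain was paired with that with the largest loss. Starts or ends over 50 bases apart counted as different. Introns were compared if any part of them lay in the span shared by both isoforms, also those running past the start or end of the other isoform. Transcript classes were compared with an exact McNemar test, shares were given exact Clopper-Pearson 95% intervals that cover counting error only, and lengths were tested with a two-sided sign-flip permutation test with 100000 resamples. Exonic overlap of named genes with other genes was taken from the same annotation.

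Named genes were chosen by a rule set before the data were examined. They are the 12 genes with the largest absolute usage difference, the 6 with the highest and the 6 with the lowest ratio of gene level, and up to 4 per gene list by usage difference, with predicted models passed over in the first parts, which gave 29 genes, of which 1 is not reported here. Alternatives were a q of 0.01, a difference over 0.2, no minimum difference, a gene level of at least 5 TPM in both conditions, whole transcript length and a tolerance of 200 bases for ends. Others were added after the data were seen. On simulated data for 195 genes of this comparison, the implied log2 level had a median absolute error of 0.00729 and a highest error of 0.0685. Each simulated gene had more than 1 listed isoform with balanced fractions. In the data 112 genes have 1 listed isoform, and fractions can be as low as 0.007 (Pknox1 in BMP2), so errors there can be larger. The spread between isoforms of a gene reached 12.7% in BMP2. All 60 genes simulated with a 4-fold change were called with the right sign, and 0 unchanged genes were. The sign-flip test was under 0.05 in 6.5% of 200 simulated null sets of 52 normally distributed values. The coding length differences in the data include a far larger value, that of Utrn, so this rate may not hold for them. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and SciPy 1.17.1 were used.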

Results

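Mouse duodenal crypt organoids, self-organising cultures of small intestinal epithelium, were given vehicle or 100 ng/ml BMP2 on day 6 for 24 h, and bulk RNA sequencing was used to follow which transcript isoforms each gene used. BMP2 is a secreted ligand of the bone morphogenetic protein pathway, which is active toward the villus tip in the intestine. The design holds 6 libraries from wild-type C57BL/6 organoids, 3 per condition. The values used here are the authors' means per condition, so no value below carries a replicate error, and the depth of the libraries is unknown. Isoform usage is the share of a gene's transcripts that an isoform makes up. Whether a usage change exceeded the spread between libraries is read from the authors' q-values.

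The comparison of BMP2 with vehicle asked which isoforms change in use when the epithelium is exposed to this differentiation signal. By the authors' q-values, isoform use differed between BMP2 and vehicle in the DNA replication genes Gins1 and Gins2 and the cell cycle transcription factor E2f1. It also differed in the brush border actin bundler Espn, the splicing factor Srsf3 and the tight junction gene Cldn7. The Gins2 values are uncertain because of an overlapping gene, and the implied gene level of E2f1 in BMP2 was 1.17 TPM. The isoforms that rose in Gins1 and Cldn7 are short models of 339 and 373 bases. Their values may depend on how reads were divided with longer isoforms. The authors' deposited table lists 302 isoforms of 202 genes past a q of 0.05 and an absolute usage difference of 0.1. Usage rose with BMP2 for 136 of these isoforms and fell for 166, so 45.0% rose (exact binomial 95% interval 39.3% to 50.8%). Fractions of a gene sum to 1, so its isoforms are tied to each other, which the interval does not allow for. The absolute difference in usage fraction in the authors' deposited table ranged from 0.101 to 0.751, with a median of 0.2015. A single isoform was listed for 112 genes, 2 isoforms for 82 genes and 3 or more for 8 genes. In each of the 90 genes with more than 1 listed isoform, at least 1 rose and at least 1 fell, which the fixed sum of fractions favours. The most used listed isoform differed between conditions in 37 of these 90 genes, among them E2f1, Gins1, Bfar, Gins2, Ldb3, Bcat2, Srsf3 and Adh7. An unlisted isoform could not have ranked higher in 29 of the 37. With a usage difference over 0.2 required, 153 isoforms of 118 genes and 32 genes with opposite changes were left.

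**Figure D1:**
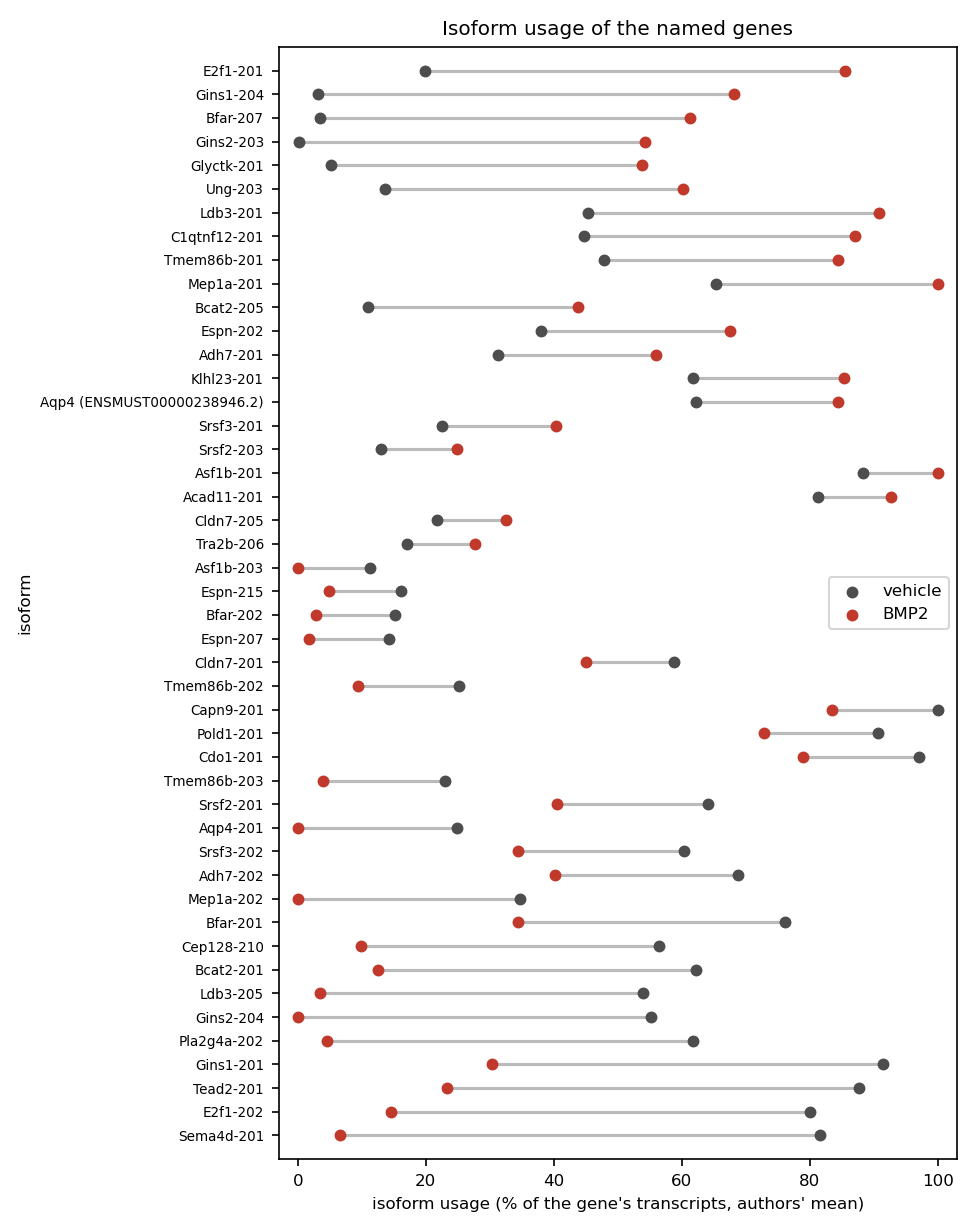
Isoform usage in percent of the gene's transcripts (x axis) for each listed isoform of 28 named genes (y axis), ordered by the change, with grey points for vehicle and red points for BMP2, each the authors' mean of a condition. E2f1-201 goes from 19.9% to 85.5% at the top, and Sema4d-201 from 81.6% to 6.6% at the bottom.

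The largest single change was in Sema4d, which encodes a transmembrane semaphorin (chromosome 13, 51685529 to 51793747, minus strand, GRCm38). Its protein-coding isoform Sema4d-201 fell from 81.6% of the gene's transcripts in vehicle to 6.6% in BMP2 (authors' deposited table, q = 0.000619). E2f1, a transcription factor of the G1 to S transition (chromosome 2, 154559407 to 154569892, minus strand, GRCm38), exchanged its isoforms. E2f1-202 fell from 80.1% to 14.5% and E2f1-201 rose from 19.9% to 85.5%, with q = 0.000731 and q = 0.00147 in the authors' deposited table. The annotated first exon of E2f1-202 spans 154569489 to 154569892 and that of E2f1-201 spans 154569067 to 154569720, while the introns after the second exon are shared. The annotated coding length is 1290 bases in E2f1-202 and 1155 bases in E2f1-201. Mean abundance was lower with BMP2 for both, from 6.88 to 0.188 TPM for E2f1-202 and from 1.70 to 0.986 TPM for E2f1-201.

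Both listed subunit genes of the GINS complex, which is part of the replicative helicase, changed. Gins1-201, the protein-coding isoform of Gins1 (chromosome 2, 150905400 to 150931280, plus strand, GRCm38), fell from 91.4% to 30.4%, with q = 5.82e-22 in the authors' deposited table. The 339-base processed transcript Gins1-204 rose from 3.2% to 68.2%, and its mean abundance was 0.589 TPM in vehicle and 3.95 TPM in BMP2. In Gins2 (chromosome 8, 120578633 to 120589304, minus strand, GRCm38) the listed isoforms are both annotated as retaining an intron. Gins2-204 fell from 55.2% to a listed 0 and Gins2-203 rose from 0.2% to 54.2%, with q = 1.84e-39 and q = 1.78e-11 in the authors' deposited table. Exons of Gins2-203 share 2758 of its 3662 bases with Gse1 on the opposite strand, and the strand setting of the quantification is not given in the sources used here, so the Gins2-203 values are uncertain. Each exon of Gins2-204 overlaps an exon of Gins2-203, so the Gins2-204 values are uncertain as well. Ung-203, of the uracil-DNA glycosylase gene Ung, rose from 13.6% to 60.2%.

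Bfar, an apoptosis regulator with a RING domain (chromosome 16, 13671858 to 13703612, plus strand, GRCm38), held the largest gain of any listed isoform annotated as retaining an intron. Bfar-207, a model of 787 bases in 2 exons between 13691965 and 13697506, rose from 3.4% to 61.3%, while the protein-coding Bfar-201 fell from 76.2% to 34.4% (authors' deposited table, q = 2.95e-45 and q = 1.29e-10). Mean abundance of Bfar-207 was 0.402 TPM in vehicle and 20.2 TPM in BMP2, and that of Bfar-201 was 9.13 and 11.2 TPM. Bcat2, a mitochondrial branched-chain aminotransferase, had the same implied gene level to within 1.01-fold, yet Bcat2-201 fell from 62.2% to 12.6% and the intron-retaining Bcat2-205 rose from 10.9% to 43.8%. Ldb3, a PDZ and LIM domain gene, moved from Ldb3-205 to Ldb3-201, whose usage rose from 45.4% to 90.8%. Ldb3-201 holds an exon from 34576986 to 34577344 on chromosome 14 (GRCm38) in place of 3 exons of Ldb3-205. Glyctk-201, of the glycerate kinase gene, rose from 5.2% to 53.8%. The listed isoforms of Tead2, Pla2g4a and Cep128 fell, from 87.7% to 23.3%, from 61.8% to 4.6% and from 56.4% to 9.8%. Of the 12 genes with the largest usage differences, 7 had an implied gene level under 5 TPM in a condition and drop out when that level is required. In BMP2 the level was 2.01 TPM for Sema4d, 1.17 for E2f1, 1.04 for Tead2, 1.68 for Pla2g4a, 1.01 for Cep128 and 2.40 for Ung, and in vehicle it was 2.84 TPM for Glyctk. Glyctk-201 shares 51.9% of its exonic bases with D030055H07Rik on the opposite strand, and Bcat2-201 and Bcat2-205 share 13.9% and 16.8% with 0610005C13Rik, so these values are uncertain. The overlap was 150 bases for Bfar-201, 13 bases for Tead2-201 and 0 bases for Bfar-207.

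Usage can change with or without a change in the level of the gene. Dividing the summed mean TPM of the listed isoforms by their summed usage gave an implied level for 195 of the 202 genes. No test across libraries was possible for these levels, and they are given as values. The level was over 2-fold higher in BMP2 for 22 genes and over 2-fold lower for 62, with a median log2 ratio of -0.12. Among genes with a usage q under 0.01 in the authors' deposited table, 14 were over 2-fold higher and 45 over 2-fold lower. Among genes at 5 TPM or more in both conditions, a filter that itself removes genes with low levels in BMP2, 16 were over 2-fold higher and 25 over 2-fold lower.

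The highest ratios belonged to Capn9, a digestive tract calpain, at 1.18 TPM in vehicle and 9.89 TPM in BMP2, and to C1qtnf12, a secreted C1q/TNF-related protein, at 4.30 and 30.8 TPM. Acad11, an acyl-CoA dehydrogenase, stood at 17.6 and 96.0 TPM, Espn at 31.5 and 144.1 TPM, Tmem86b, a lysoplasmalogenase, at 7.30 and 30.6 TPM, and Adh7, an alcohol dehydrogenase, at 1.41 and 5.71 TPM. In 5 of these 6 genes a protein-coding isoform gained usage, but other protein-coding isoforms of Espn and Tmem86b lost usage. C1qtnf12, Acad11 and Capn9 have a single listed isoform. C1qtnf12-201 rose from 44.7% to 87.0%, Tmem86b-201 from 47.9% to 84.4%, Adh7-201 from 31.2% to 56.0% and Acad11-201 from 81.3% to 92.7%, whereas Capn9-201 fell from 100% to 83.5%. Among the lowest ratios were those of Klhl23, at 124.9 TPM in vehicle and 1.53 TPM in BMP2, of the water channel gene Aqp4, at 56.4 and 1.10 TPM, and of the cysteine dioxygenase gene Cdo1, at 39.9 and 1.80 TPM. They were followed by the histone chaperone Asf1b at 22.2 and 1.26 TPM and the DNA polymerase delta subunit Pold1 at 24.4 and 1.56 TPM. Usage of Pold1-201 fell from 90.6% to 72.9%. Asf1b-201 rose from 88.3% to 100% as Asf1b-203 reached a listed 0. Acad11-201 shares 13.9% of its exonic bases with Ackr4 and Tmem86b-201 shares 13.5% with Gm44877, both on the opposite strand, so these values are likewise uncertain, and the overlap of Adh7-201 was 3.15%.

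**Figure D2:**
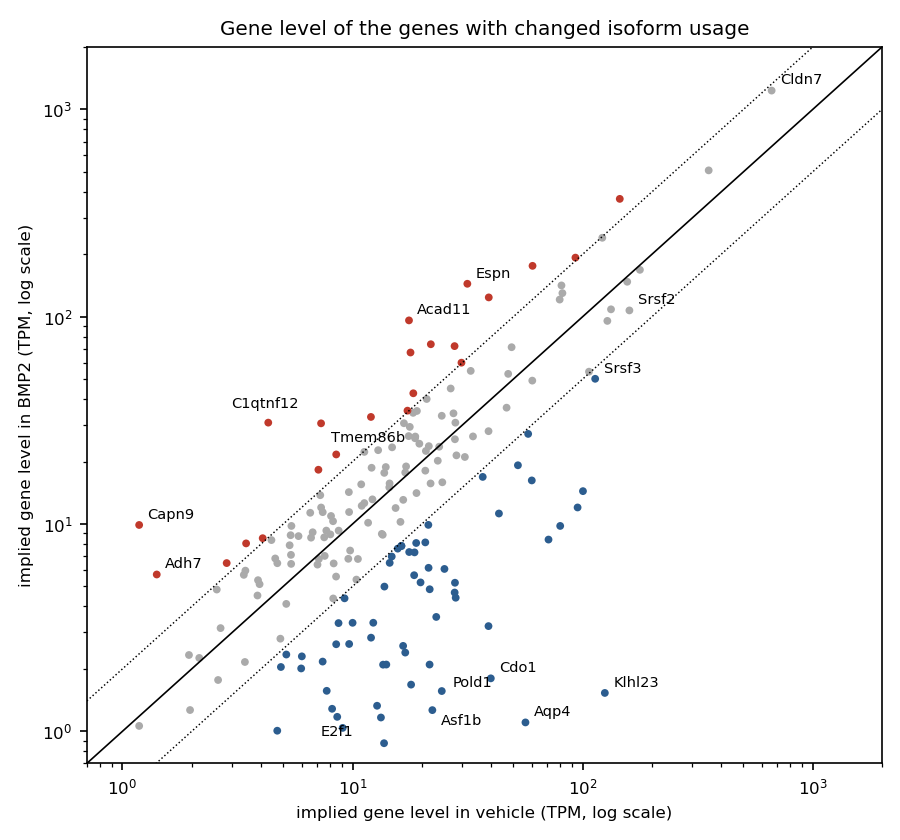
Implied gene level in vehicle (x axis) against BMP2 (y axis) in TPM on log scales for 195 genes with changed isoform usage, from the authors' means. Red points are over 2-fold higher in BMP2 (22 genes), blue points over 2-fold lower (62 genes), the solid line marks equal levels and the dotted lines a 2-fold difference.

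An isoform that gained usage was not always more abundant. Of the 136 isoforms with a usage gain, mean TPM was higher in BMP2 for 106 and lower for 30. Of the 166 with a usage loss, it was lower for 133 and higher for 33.

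Of the 13 gene lists fixed before the data were examined, 4 held genes with changed isoform usage. The enterocyte and brush border list had 2 of its 40 genes in the authors' deposited table, Espn and Mep1a, with implied levels that lay apart in direction. Espn, an actin-bundling protein of microvilli (chromosome 4, 152120331 to 152152371, minus strand, GRCm38), gained the isoform Espn-202, from 38.0% to 67.5% and from 11.9 to 97.2 TPM (authors' deposited table, q = 7.8e-15). Espn-207 fell from 14.3% to 1.7% and the processed transcript Espn-215 from 16.1% to 4.8%. The annotated first exon of Espn-202 lies at 152128770 to 152128925, and that of Espn-207 at 152131789 to 152131865. Mep1a, the alpha subunit of the brush border metalloprotease meprin, was at 8.49 TPM in vehicle and 2.63 TPM in BMP2. Mep1a-201 rose from 65.3% to 100% and Mep1a-202 fell from 34.7% to 0, although the annotated models have the same introns and differ by 39 bases at the start and 7 bases at the end.

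The RNA splicing regulator list had 3 of its 67 genes in the authors' deposited table, Srsf3, Srsf2 and Tra2b, and in all 3 the isoform that rose is annotated as subject to nonsense-mediated decay or as retaining an intron. Srsf3-201 (chromosome 17, gene at 29032628 to 29043373, plus strand, GRCm38) contains an additional exon of 456 bases at 29039454 to 29039909. Its usage rose from 22.5% to 40.4%, while Srsf3-202 fell from 60.3% to 34.4% (authors' deposited table, q = 1.58e-05 and q = 1.17e-10). Mean abundance of Srsf3-202 was 68.4 TPM in vehicle and 17.4 TPM in BMP2, and that of Srsf3-201 was 25.5 and 20.2 TPM. Srsf2-203 rose from 13.0% to 24.8% and Srsf2-201 fell from 64.1% to 40.5% (authors' deposited table, q = 1.55e-13 and q = 8.14e-13). Tra2b-206 rose from 17.1% to 27.7% with q = 0.0192 in the authors' deposited table, and its mean abundance was 18.2 TPM in vehicle and 15.0 TPM in BMP2. Implied gene levels in vehicle and BMP2 were 113.4 and 50.2 TPM for Srsf3, 159.7 and 107.2 TPM for Srsf2 and 106.5 and 54.3 TPM for Tra2b. Srsf2-203 shares 24.8% of its exonic bases with Mettl23, and Srsf2-201 shares 24.2% with Mettl23 and 15.2% with Mfsd11, all on the opposite strand, so the Srsf2 values are uncertain.

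The cytoskeleton, junction and adhesion list had 1 of its 67 genes in the authors' deposited table, Cldn7, a claudin with an implied level of 662.8 TPM in vehicle and 1233 TPM in BMP2. Cldn7-201 fell from 58.7% to 45.1% and Cldn7-205, a shorter model that starts 1522 bases downstream, rose from 21.8% to 32.6%. Cldn7-205 has 373 bases, and each of its exons overlaps an exon of Cldn7-201. Its value therefore depends on how reads were divided between these isoforms. E2f1 was the only gene of the 30 on the cell cycle list in that table. The table used here held no member of the lists for the BMP and SMAD pathway, stem and progenitor cells, the Wnt pathway, lipid metabolism, intestinal transcription factors, secretory cells, gastric and pyloric mucosa, mesenchymal, immune, endothelial and neural cells, or stress and RNA quality, so their isoform usage was not analysed here.

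**Figure D3:**
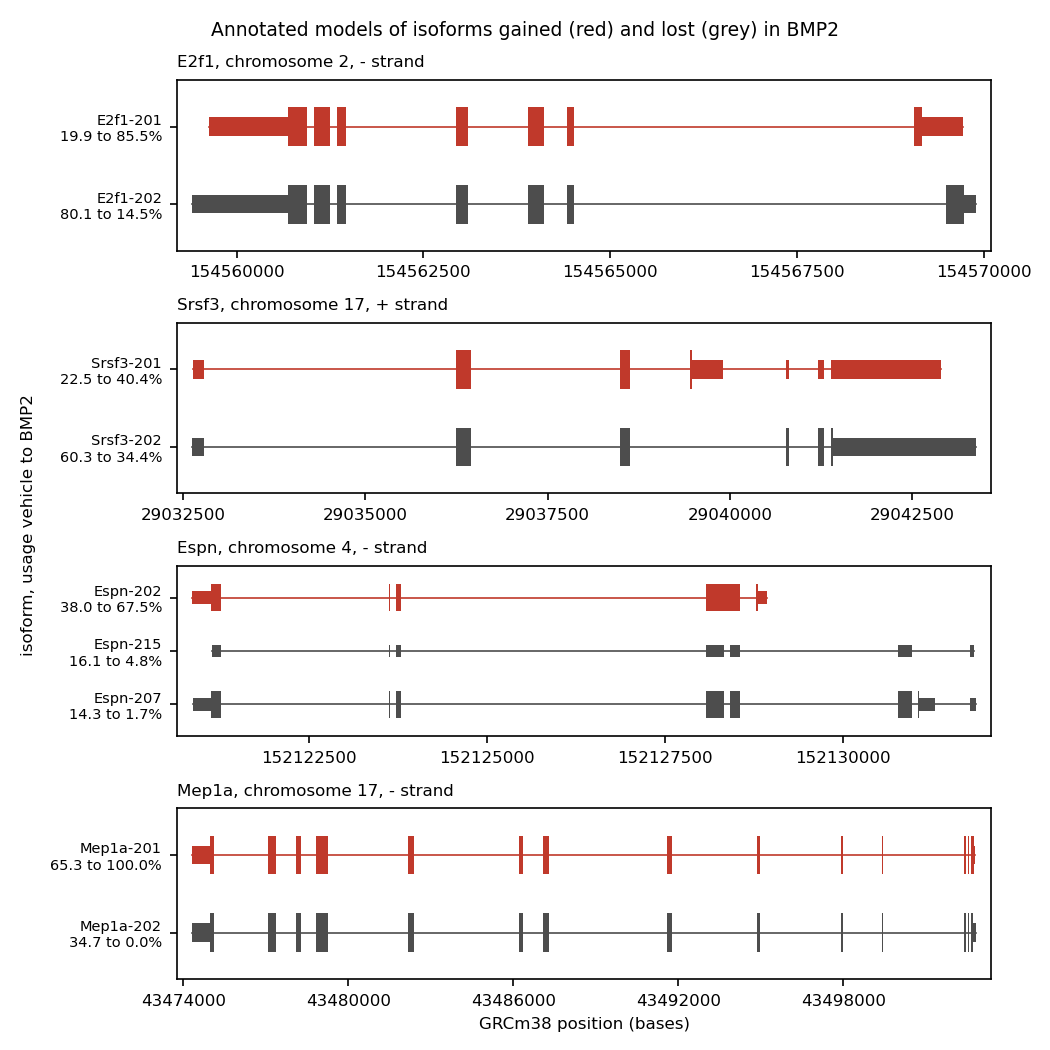
Annotated exons of the listed isoforms of E2f1, Srsf3, Espn and Mep1a along GRCm38 positions in bases (x axis), with tall boxes for coding sequence, low boxes for other exonic sequence, red for isoforms whose usage rose with BMP2 and grey for those whose usage fell. Labels on the y axis give usage in vehicle and BMP2, such as 22.5% and 40.4% for Srsf3-201, which holds the additional exon.

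In 87 of the 90 genes with opposite changes, the isoform with the largest gain and that with the largest loss could both be matched to the annotation. Protein-coding isoforms lost usage to other transcript classes more often than the reverse. In 27 genes, including Gins1, Bfar, Srsf3 and, with the overlaps given above, Bcat2 and Srsf2, usage moved from a protein-coding isoform to one of another class, and in 10 genes, including Adh7 and Asf1b, it moved the other way. The share was 73.0% of the 37 genes (exact binomial 95% interval 55.9% to 86.2%, two-sided exact McNemar test, p = 0.00763). Of the 27 gained isoforms, 14 are annotated as retaining an intron, 9 as processed transcripts and 4 as subject to nonsense-mediated decay, and 21 had a higher mean TPM in BMP2. Both isoforms were protein-coding in 47 genes, including E2f1, Ldb3, Espn, Mep1a, Tmem86b and Cldn7, and neither was in 3, including Gins2. Over all listed isoforms, the retained intron class had 19 with higher and 8 with lower usage, and the protein-coding class 92 and 143. The share was 78.6% with p = 0.0574 (exact test) when a usage difference over 0.2 was required, which left 14 genes, and 68.2% with p = 0.134 (exact test) in the 22 genes whose isoforms overlap other genes by at most 5% of their exonic bases. It was 71.4% with p = 0.0784 (exact test) in genes at 10 TPM or more. In genes whose implied level was higher in BMP2 by any amount, it was 73.3% with p = 0.118 (exact test). Genes are not replicates, so these p-values describe the genes listed.

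**Figure D4:**
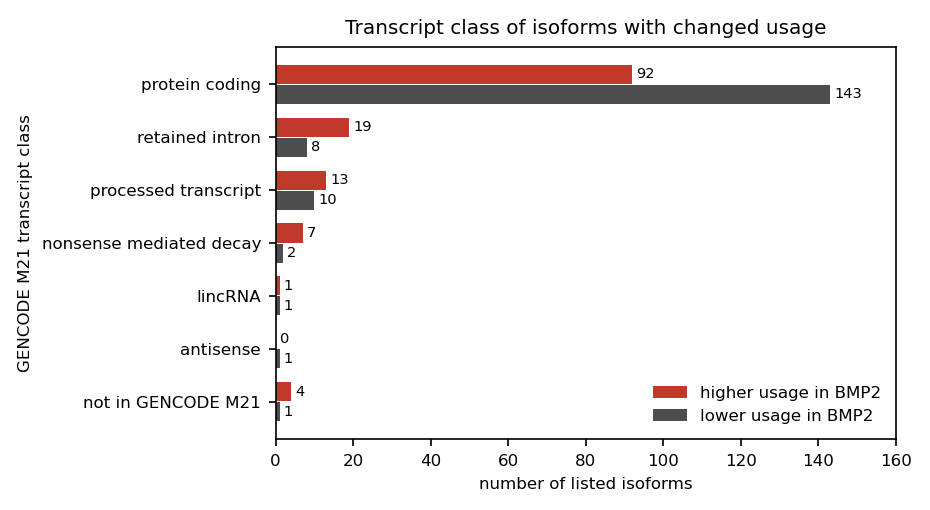
Number of listed isoforms (x axis) in each GENCODE M21 transcript class (y axis), with red bars for higher and grey bars for lower usage in BMP2. Protein-coding isoforms number 92 and 143, and isoforms annotated as retaining an intron 19 and 8.

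No difference in coding length between gained and lost isoforms passed the test. Among 52 genes in which both isoforms had an annotated coding sequence, as in E2f1, it was shorter in the gained isoform in 29, longer in 19 and equal in 4. Lengths here include models annotated with a start or end not found, which may be incomplete. The mean difference was -51.4 bases and the median -64.5 bases (two-sided sign-flip permutation test of the mean, p = 0.831). The mean was 137.6 bases with a usage difference over 0.2 and 27.0 bases at a gene level of 5 TPM or more, with p = 0.873 and p = 0.918 in the same permutation test. Both positive means rest on Utrn, with 10290 coding bases in the gained and 2868 in the lost isoform. The mean over all 52 genes includes Utrn as well and is less negative because of it. The test of that mean shares this limit. The medians at these thresholds were -7 and -66 bases. The whole transcript was shorter in the gained isoform in 54 of 87 pairs, with a mean difference of -348 bases (same permutation test, p = 0.126). Among pairs with a q under 0.01 in the authors' deposited table it was shorter in 42 of 60, with a mean of -596 bases, which passed the test (p = 0.0221, permutation), a combination of whole length and threshold added after the data were seen. The mean was -126.5 bases with a usage difference over 0.2 and -356 bases at 5 TPM or more, and neither passed (permutation, p = 0.774 and p = 0.141). In 25 of the 27 genes that moved from a protein-coding isoform to another class the gained isoform was shorter. In most of the 10 genes that moved the other way, such as Adh7 and Asf1b, the isoform of the other class was likewise the shorter one. The difference in whole length is therefore not independent of the shift in class.

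Gained and lost isoforms most often differed in several of the parts compared, though these parts are not independent. The annotated transcript start differed by over 50 bases in 67 of 87 pairs, or 77.0% (exact binomial 95% interval 66.8% to 85.4%), as in Espn and Cldn7. The annotated end differed in 63 pairs, or 72.4% (61.8% to 81.5%), as in Srsf3. Introns lying at least partly within the shared span differed in 81 pairs, or 93.1% (85.6% to 97.4%). An intron that runs past the start or end of the other isoform counts here. A different start or end can therefore make the introns differ by itself, as the start does in Bfar, Bcat2 and Cldn7. Counted this way, all 3 parts differed in 43 pairs, including E2f1, Gins1, Bfar and Bcat2. By the same count a single part differed in few pairs, with 1 pair for the start, 3 for the introns and 0 for the end. Some models are annotated with a start or end not found. Without them, 34 of the 47 pairs of protein-coding isoforms were left. The differences in start, end and introns were not recomputed without these models and may partly reflect incomplete annotation. Each listed isoform belongs to a gene that the authors' deposited table marks as having a predicted consequence of the switch, so pairs without one do not enter these shares.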

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

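The class comparisons at 10 TPM, in genes higher in BMP2 by any amount and without overlapping genes, and whole length with other thresholds, are among 11 values added after the result was seen. Of 62 values recomputed under alternatives, 47 kept their direction and side of the threshold or stayed within 1.5 times or the interval of the value reported. The 12 without a minimum usage difference could not differ, since every listed isoform exceeds it. With a q under 0.01, 14 genes were over 2-fold higher in level. A usage difference over 0.2 left 153 isoforms of 118 genes, 32 genes with opposite changes, 20 with another most used isoform, a mean coding length difference of 137.6 bases and a coding-to-other share of 78.6% (exact test, p = 0.0574). A gene level of 5 TPM left 133 genes, without 16 of the named genes, 25 over 2-fold lower, and a mean coding difference of 27.0 bases. These come from fewer isoforms by construction. The positive coding means rest on Utrn, with 10290 coding bases in the gained and 2868 in the lost isoform. The mean at the main thresholds includes it too. The median coding difference stayed negative, at -7 bases with a usage difference over 0.2 and -66 bases at 5 TPM. Whole transcripts differed by a mean of -596 bases with a q under 0.01 (permutation test, p = 0.0221), and by -126.5 and -356 bases with the other thresholds (p = 0.774 and p = 0.141). With a tolerance of 200 bases, 62.1% of pairs differed in start. The coding-to-other share was 71.4% at 10 TPM or more, 73.3% in genes higher in BMP2 by any amount and 68.2% without overlapping genes (exact tests, p = 0.0784, p = 0.118 and p = 0.134), each on fewer genes. No paired analysis was possible because the table used holds means per condition. For the same reason leaving out replicates, the replicate block, other tools, normalizations and count filters, and pseudocounts were not run. A gene level threshold regardless of q was the reported setting. Depth is unknown, so its limits on low fractions could not be derived.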

Other observations

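The tests in this part were all chosen after the results were seen, except the class comparison at 5 TPM, and so were the genes named here that the report does not name. Mxi1, an antagonist of Myc, had an implied level of 60.6 TPM in vehicle and 175.9 TPM in BMP2, and usage rose for Mxi1-201 from 67.4% to 83.8% and fell for Mxi1-203 from 31.1% to 13.0%. The annotated coding length is 885 bases in Mxi1-201 and 684 bases in Mxi1-203. Gpt, the cytosolic alanine aminotransferase, stood at 21.9 and 73.6 TPM, and Gpt-201 rose from 47.7% to 71.9%. Elovl1, a fatty acid elongase, moved among 3 isoforms with the same annotated coding length of 837 bases, with Elovl1-202 rising from 7.4% to 23.9%. Rab11fip3, an effector of Rab11 in recycling endosomes, moved from Rab11fip3-203, with 3276 coding bases, to Rab11fip3-201, with 1332, whose usage rose from 54.8% to 84.8%. In Hyal2, a hyaluronidase gene, Hyal2-207 rose from 8.8% to 25.5% with a coding length of 1419 bases in both listed isoforms. Rab11fip3-201 and Rab11fip3-203 share 15.7% and 9.57% of their exonic bases with 1700022N22Rik on the opposite strand. Mxi1-201 and Mxi1-203 share 7.38% and 8.29% with Gm10197, also on the opposite strand, so the values of both genes are uncertain.

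The smallest q of the authors' deposited table, 3.3e-62, belonged to Gm46430-210 of the long noncoding RNA gene Gm46430, which fell from 86.7% to 41.5% as Gm46430-207 rose from 10.3% to 44.2%. The implied level of Gm46430 was 100.3 TPM in vehicle and 14.4 TPM in BMP2. Both Acp2 isoforms that fell, from 38.5% to 18.4%, have identical values in every column but the rank, and cannot be told apart in this table.

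Usage moved from protein-coding isoforms to other classes in 27 genes and back in 10. If a gene level under 5 TPM were the cause, the excess would be gone above that level, and the share there was 75.9% (exact 95% interval 56.5% to 89.7%, 29 genes), which argues against it as the whole cause. At 10 TPM or more the share was 71.4% (47.8% to 88.7%, 21 genes). That interval reaches below 50%, so a part played by levels under 10 TPM stays open. If reads were assigned to short annotated fragments, it would be gone where the other isoform has at least 0.5 times the length of the coding one. The share was 80.0% (51.9% to 95.7%, 15 genes), which argues against that as the whole cause over these genes. Bfar, Gins1 and Bcat2, whose gained isoforms are shorter than that, are not among them, so for these switches the explanation stays open. Some of the genes kept, such as Srsf2 and Psmg3, overlap other genes. Lower precision where a gene is low in BMP2 stays open (73.3% in genes higher in BMP2 by any amount, 44.9% to 92.2%, 15 genes). Reads shared with overlapping genes stay open too (68.2% without such genes, 45.1% to 86.1%, 22 genes). Both intervals reach below 50%. An effect of BMP2 on splicing or on the decay of these isoforms may also account for the shift and was not tested.

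Gins2-203 and Gse1-201, on opposite strands, gained usage together and share 2758 exonic bases. Gse1-201 rose from 25.3% to 65.8%, and from 1.34 to 5.81 TPM, while Gins2-203 was at 0.0650 TPM in vehicle and 2.82 TPM in BMP2. Reads of Gse1 counted for Gins2 are a candidate explanation for the Gins2-203 gain, which would need Gins2-203 to stay below Gse1-201, and the ratio was 0.0484 in vehicle and 0.486 in BMP2. Gins2-203 was 43.4-fold higher in BMP2 and Gse1-201 4.33-fold, which goes against a constant share of Gse1 reads, but the vehicle value is close to 0, no replicate error is at hand and the strand setting is not given in the sources used here, so the gain stays open. Gins2-204, which fell from 15.4 TPM to a listed 0, shares 0 exonic bases with other genes. Each of its exons overlaps an exon of Gins2-203, however. Its value therefore depends on how reads were divided between these isoforms, and its fall stays open as well.

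Some further genes of DNA replication and repair were picked from the table after their levels were seen, and they were not tested as a group. Cdt1 was at 28.1 TPM in vehicle and 4.41 TPM in BMP2, Pclaf at 71.1 and 8.41 TPM, and Brca1 at 8.15 and 1.28 TPM, while Shld1 was at 5.41 and 6.42 TPM.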
